A study of Mus musculus with 8 samples.

How the data were processed

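RNA sequencing was done on bone marrow-derived macrophages of C57BL/6 mice, which are macrophages grown in culture from marrow precursors. The labels describe 4 libraries from cells kept in medium lacking serine and glycine and 4 control libraries from cells in normal medium. Total RNA was extracted with Trizol and captured on oligo-dT beads, per the labels' protocols. The labels do not say whether the cells were stimulated, how long serine and glycine were withheld, or whether the libraries came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical.

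The authors deposited a table of 17492 genes that holds, for each library, estimated counts, FPKM and TPM. BWA, Bowtie2 and RSEM and the mouse build GRCm38.p6 are named in the submitters' processing notes, and tool versions are not given in the sources used here. The deposited estimated counts are the input of all tests; 8.06% to 8.47% of their values per library were not whole at a tolerance of 1e-06, and they were rounded to whole numbers. FPKM, by the authors, served only to derive each gene's effective length from its ratio to the counts. The TPM values deposited by the authors, scaled to the same sum in each library, were used for no test. The 6 columns of group averages were not used. The table held no row for mitochondrially encoded genes and 1 of the 11 genes of a list of nuclear RNAs, so RNA quality was not analysed here through those genes. Coordinates are those of an annotation of the same build, matched by Entrez ID for 17380 genes.

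Library totals lay between 17565291 and 18201599 counts, so that 3 counts, the most that a count of 0 allows, correspond to 0.165 to 0.171 CPM (reads scaled to a common library total). This covers counting error only. Genes were kept with edgeR's filter (minimum count 10, minimum total 15), which left 11700. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values are on that scale. The groups were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05, 4 libraries against 4 with 6 residual degrees of freedom. Fold changes are log2 of serine/glycine-free over control, with the standard error (SE) derived from the F statistic.

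Gene lists for pathways, macrophage states and other cell types, 48 in all, were fixed before the data were examined, and 43 had at least 3 tested members. Each was compared with the other genes by camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 43 lists, and again with an estimated correlation. Named genes followed a rule fixed at the same time. It took 21 genes set in advance, the 8 largest rises and the 8 largest falls. The rises and falls were ranked among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. Predicted genes, pseudogenes and immunoglobulin or T-cell receptor segments were left out of that ranking. The rule allowed up to 4 members of each list with the smallest adjusted p, and 3 were taken. Some genes and 1 list that these rules selected are not reported here, and the screen for outlying libraries did not count those genes. Genes chosen after their values were seen are named as such in the closing section and among the cholesterol efflux genes.

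The alternatives planned before the data were examined were DESeq2's RLE size factors, library size alone, no filter, a mean of at least 5 CPM, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, a log2 change of at least 1, an estimated correlation and fry. Removal of each library's trend with gene length or with mean expression was added after seeing the data. The steps were tested on simulated data: of 66 genes changed by each fold among 11634, 62.1% of the 1.2-fold, 92.4% of the 1.5-fold and 100% of the 2-fold changes were recovered, and 3.45% of calls were false. The simulation changed 200 genes, against 3882 that passed in the data. The adjustment was therefore stricter on raw p there, and these shares do not give the recovery in the data. A planted list of 25 genes raised by 0.2 on the log2 scale was found, and 0 of 40 unchanged lists were called. The simulated genes varied independently, so this does not show how camera behaves on lists with correlated members. In the data the estimated correlation reached 0.38, for oxidative phosphorylation genes. In counts simulated with a length trend, false calls numbered 263 before and 6 after the trend was removed. That trend was linear and equal in all libraries of a group, whereas slopes in the data differed between libraries of a group. How well the removal works on such uneven trends was not simulated.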

Results

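Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, in 4 libraries from medium without serine and glycine and in 4 control libraries from normal medium. Total estimated counts lay between 17565291 and 18201599 per library. Within groups, all 12 pairs of libraries differed by more than sampling noise, with chi-square per degree of freedom between 1.42 and 3.59, so no library was counted as a copy of another. The common coefficient of variation within groups, from edgeR's dispersion, was 2.78%. These values do not tell separate cultures or animals from repeated preparations of the same RNA. The first principal component, with 69.3% of the variance, separated the groups, and the second, with 9.02%, set replicate 4 of the serine/glycine-free group apart.

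The comparison asks how macrophages differ when serine and glycine are withheld, with IGF1, the kinase p38 and polarization named in the series title. Without serine and glycine, macrophages had higher transcripts of NRF2 targets, lysosomal proteins, cholesterol synthesis enzymes and matrix remodelling genes. A joint list of targets of the oxysterol receptor LXR and cholesterol efflux genes was also higher. Transcripts of type I interferon-stimulated genes and genes of the unfolded protein response were lower. Igf1 rose from 103 ± 2.19 to 146 ± 6.40 CPM (SD, n = 4), and Mapk14, which encodes p38 alpha, fell from 203 ± 3.85 to 178 ± 4.79 CPM. Most changes were small: the median fold among changed genes was 1.15. Of 11700 genes tested, 3882 passed an adjusted p of 0.05 (edgeR quasi-likelihood), 1855 higher and 2027 lower. At least 1.5-fold, 267 rose and 94 fell. At least 2-fold, 65 rose and 16 fell, but only 16 of these rises and 2 of these falls had a mean of at least 5 CPM. The groups did not overlap for 30.6% of tested genes, against 2.86% by chance.

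**Figure D1:**
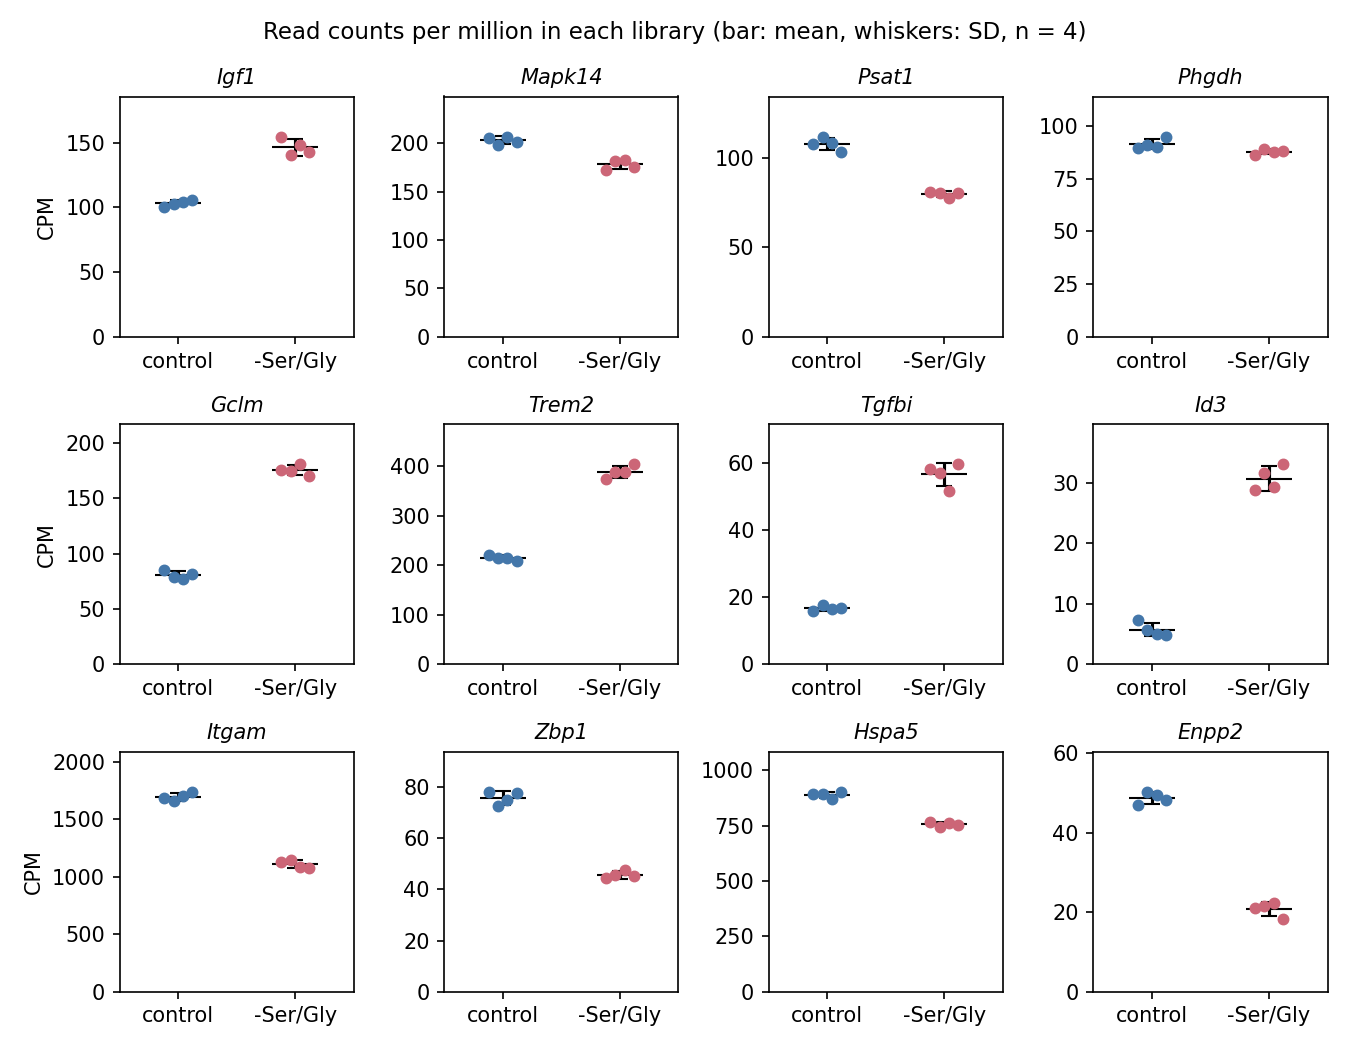
CPM (vertical axis, from 0) of 12 genes in the 4 control and 4 serine/glycine-free libraries; each point is a library, the bar the mean and the whiskers the SD. Igf1 means were 103 and 146 CPM, and Tgfbi means 16.6 and 56.5 CPM, in control and serine/glycine-free libraries.

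Among genes with a mean of at least 5 CPM, the largest rise was that of Id1, an inhibitor of basic helix-loop-helix transcription factors, from 1.57 ± 0.654 to 8.72 ± 0.802 CPM (SD, n = 4; log2 change 2.47, SE 0.16, adjusted p = 7.4e-13). The related Id3 rose from 5.71 ± 1.09 to 30.7 ± 2.0 CPM (log2 change 2.42), with non-whole estimated counts in 75% of libraries, so its level is uncertain where reads were split between loci. Tgfbi, a secreted matrix protein induced by TGF-beta, rose from 16.6 ± 0.780 to 56.5 ± 3.52 CPM (log2 change 1.76, SE 0.053, adjusted p = 2.3e-28). The other large rises were Adgb (log2 change 1.82), Tmem37 (1.67), Chst1 (1.28), Arhgap22 (1.28) and Tmeff1 (1.25). Enpp2, which encodes the lysophospholipase D autotaxin, showed the largest fall, from 48.7 ± 1.51 to 20.8 ± 1.79 CPM (log2 change -1.23, SE 0.052, adjusted p = 4.4e-23). Serpina3g followed with a log2 change of -1.06. It belongs to a family of close paralogs, its counts were not whole in 12.5% of libraries, and its level is uncertain to that extent. Of the genes named below, Slc3a2, Ifit3 and Tyms had non-whole counts in 100% of libraries and Ogdh and Ctsl in 25%, with the same limit. The summed counts of H2-DMb1 and Pltp, also named below, were not whole in either group. Scarf2 (-0.98), Asb2 (-0.86), Garnl3 (-0.81), Camkk1 (-0.79) and Lifr (-0.77) also fell. On GRCm38.p6, Id1 (Entrez 15901) lies on chromosome 2 at 152736251 to 152737410. Tgfbi (21810) lies on chromosome 13 at 56609586 to 56639359, and Enpp2 (18606) on chromosome 15 at 54838901 to 54952789. All are annotated as protein-coding genes.

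Among enzymes of serine synthesis, Psat1 fell from 108 ± 3.46 to 79.6 ± 1.5 CPM (SD, n = 4; log2 change -0.43, SE 0.034, adjusted p = 2.5e-14). Phgdh, the first enzyme of the pathway, had a log2 change of -0.056 (adjusted p = 0.20), and Psph of 0.0068 (adjusted p = 0.956), neither past the threshold. With each library's trend with gene length removed, Phgdh passed (-0.098, adjusted p = 0.0107). The serine hydroxymethyltransferase Shmt2 fell (-0.13, adjusted p = 0.0022), while Shmt1 stood at -0.13 (adjusted p = 0.164). The list of serine and glycine synthesis also held genes of other steps, such as the glycine cleavage system. Of its 10 tested genes, 2 rose, 3 fell and 5 did not pass, the same adjusted over the list alone. The 2 that rose were Gcsh of the glycine cleavage system (0.22) and Gcat (0.21). None of Phgdh, Psat1, Psph, Shmt1 and Shmt2 rose past the threshold. The list did not pass camera (adjusted p = 0.455). Of 21 folate and one-carbon genes, 5 rose, 6 fell and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.455): Mtr (-0.54) fell and mitochondrial Mthfd2 rose (0.29). Of 35 amino acid response genes, 11 rose, 10 fell and 14 did not pass (12 and 10 adjusted over the list alone, camera adjusted p = 0.650). Atf4, the transcription factor of that response, rose by a log2 change of 0.20 (adjusted p = 4.3e-07) and its target Asns by 0.16 (adjusted p = 0.0013), while Herpud1 fell (-0.38) and Chac1 stood at 0.19 (adjusted p = 0.499). Of 20 cytosolic tRNA synthetases, 3 rose, 2 fell and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.911). Aars rose (0.13), Cars rose (0.21) and Vars fell (-0.20). Of 18 amino acid transporters, 5 rose, 5 fell and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0887, median -0.0061, mean 0.10). With the length trend removed the list's camera adjusted p was 0.0120, and 0.145 with an estimated correlation as well. Slc7a8 (0.86), Slc3a2 (0.38) and Slc7a11 (0.56), the last a cystine importer, rose.

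Igf1 (Entrez 16000, chromosome 10, 87858265 to 87937047) changed by 0.50 on the log2 scale (SE 0.032, adjusted p = 7.1e-17), a 1.42-fold rise. Its receptor gene Igf1r stood at 0.13 (adjusted p = 0.461). Of 14 tested genes of the IGF and insulin axis, 4 rose, 6 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.920, test direction down, median 0.012). Igf2r rose (0.32) and Pik3cd fell (-0.41). Mapk14 (Entrez 26416, chromosome 17, 28691342 to 28748405) changed by -0.19 (SE 0.028, adjusted p = 5.1e-07). Of 29 genes of the p38 pathway, 5 rose, 9 fell and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.920). Mef2a (0.29) and Gadd45g (0.80) rose. These values are transcript levels and do not measure kinase activity. Of 24 classical activation genes, 6 rose, 9 fell and 9 did not pass (7 and 9 adjusted over the list alone, camera adjusted p = 0.810, test direction down, median 0.084, mean 0.049). Socs3 (-0.47) and the chemokine Cxcl10 (-0.64) fell and Ccl4 rose (0.32). Nos2 (0.094, adjusted p = 0.20) and Il1b (-0.10, adjusted p = 0.584) did not pass. Tnf changed by -0.068 (adjusted p = 0.0378), and its call was lost when any of 7 of the 8 libraries was left out, with adjusted p up to 0.0936 (without serine/glycine-free replicate 3). Il6 had 1 to 10 and Arg1 0 to 4 counts per library, too few to test, and Retnla was not analysed here. Of 20 alternative activation genes, 5 rose, 6 fell and 9 did not pass, the same adjusted over the list alone, and the list passed camera upward (adjusted p = 0.0324, median -0.036, mean 0.061; adjusted p = 0.252 with an estimated correlation). Without control replicate 4 its adjusted p was 0.0665. Its members with the smallest p were the lipid receptor gene Trem2 (0.86), the transglutaminase Tgm2 (0.84) and the beta-glucan receptor gene Clec7a (0.89), all higher, while the mannose receptor Mrc1 fell from 110 ± 4.25 to 91.0 ± 4.26 CPM (-0.28). Chil3 stood at 0.41 (adjusted p = 0.153). Of 20 NF-kappaB feedback genes, 5 rose, 8 fell and 7 did not pass (6 and 8 adjusted over the list alone, camera adjusted p = 0.455, test direction down, median 0.015, mean -0.011). Tnfaip2 rose (0.34), Nfkbiz (-0.25) and Icam1 (-0.26) fell.

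The NRF2 target list, antioxidant genes under the transcription factor NRF2, rose: 22 of 25 tested members rose, 0 fell and 3 did not pass (23 and 0 adjusted over the list alone, camera adjusted p = 2.9e-28). Gclm, a subunit of the enzyme that starts glutathione synthesis, went from 80.7 CPM to 175 CPM (log2 change 1.12, SE 0.033), with Prdx1 at 0.47 and Hmox1 at 0.44. Of 22 genes of methionine, transsulfuration and glutathione metabolism, 8 rose, 5 fell and 9 did not pass (9 and 5 adjusted over the list alone, camera adjusted p = 0.0388; adjusted p = 0.219 with an estimated correlation and 0.0516 with the length trend removed). Its call was lost without serine/glycine-free replicate 3 (adjusted p = 0.0578) and without control replicate 1 (adjusted p = 0.0546). Of 17 iron and heme genes, 11 rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 0.00011), with Slc48a1 at 0.23 and Slc11a1 at 0.16. These lists share members with the NRF2 list, among them Gclm for methionine and glutathione and Hmox1 for iron and heme. Their results are therefore not independent. Of 39 lysosomal genes, 30 rose, 1 fell and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 9.9e-17). The protease genes Ctsl (0.45) and Ctsd (0.36) and the acid lipase Lipa (0.40) rose. Of 27 autophagy genes, 10 rose, 2 fell and 15 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 0.0544). The list passed without serine/glycine-free replicate 4 (adjusted p = 0.0405) and without control replicate 2 (adjusted p = 0.0493). Sqstm1 (0.30) and Gabarapl1 (0.33) rose and Optn fell (-0.26).

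Cholesterol synthesis enzymes rose: of 24, 17 rose, 0 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 7.2e-06), with Msmo1 at 0.35 and Fdps at 0.40. Of 16 LXR and efflux genes, targets of the oxysterol receptor LXR or genes of cholesterol export, 9 rose, 1 fell and 6 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 3.3e-06). Arl4c (0.86), Nr1h3 (0.62), which encodes LXR alpha, and Npc2 (0.37) rose. Abca1, Abcg1 and Pltp of this list were chosen after their values were seen. Their estimated counts, summed over each group, went from 22909 to 24157, from 18147 to 19737 and from 81342 to 66058 without serine and glycine. Of 15 fatty acid synthesis genes, 3 rose, 1 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.452). Me1 rose (0.60), Elovl1 rose (0.16) and Fasn fell (-0.092). The call of Fasn was lost without serine/glycine-free replicate 3 (adjusted p = 0.0639), without control replicate 1 (adjusted p = 0.0578) and with the length trend removed (adjusted p = 0.515). Of 18 sphingolipid and phospholipid genes, 5 rose, 1 fell and 12 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.116), with Sptssa (0.26) and Sgms1 (0.26) higher and Ugcg lower (-0.27).

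Extracellular matrix and remodelling genes rose: of 21 tested, 15 rose, 1 fell and 5 did not pass (16 and 2 adjusted over the list alone, camera adjusted p = 1.5e-21). Gpnmb rose from 2407 to 4107 CPM (0.77) and Spp1, which encodes osteopontin, from 819 to 1328 CPM (0.70). Of 17 chemokine and growth factor receptor genes, 8 rose, 7 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0144 upward, median -0.028, mean 0.083; adjusted p = 0.219 with an estimated correlation), with Csf1r (0.41), Tgfbr1 (0.60) and Cxcr4 (0.74) higher. Of 17 macrophage identity genes, 8 rose, 7 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0183 upward; adjusted p = 0.101 with an estimated correlation and 0.0875 with the length trend removed). In that list Itgam, which encodes the integrin CD11b, fell from 1695 to 1110 CPM (-0.61). Of 28 complement and phagocytosis genes, 10 rose, 15 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.105). With the length trend removed the list's camera adjusted p was 0.0199, and 0.119 with an estimated correlation as well. The Fc receptor gene Fcgr4 fell (-0.68) and Mfge8, a bridge to dying cells, rose (0.81). Of 6 tested genes of MHC class II and its antigen processing, 3 rose, 0 fell and 3 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.104). The 3 were processing genes, and H2-Ab1, H2-DMa and H2-DMb1 did not pass. Ctss (0.27) and Cd74 (0.18) rose. Ifi30 changed by 0.10 (adjusted p = 0.0405), a call lost when any of 5 of the 8 libraries was left out, with adjusted p up to 0.196 (without serine/glycine-free replicate 4), and with the length trend removed (adjusted p = 0.710).

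**Figure D2:**
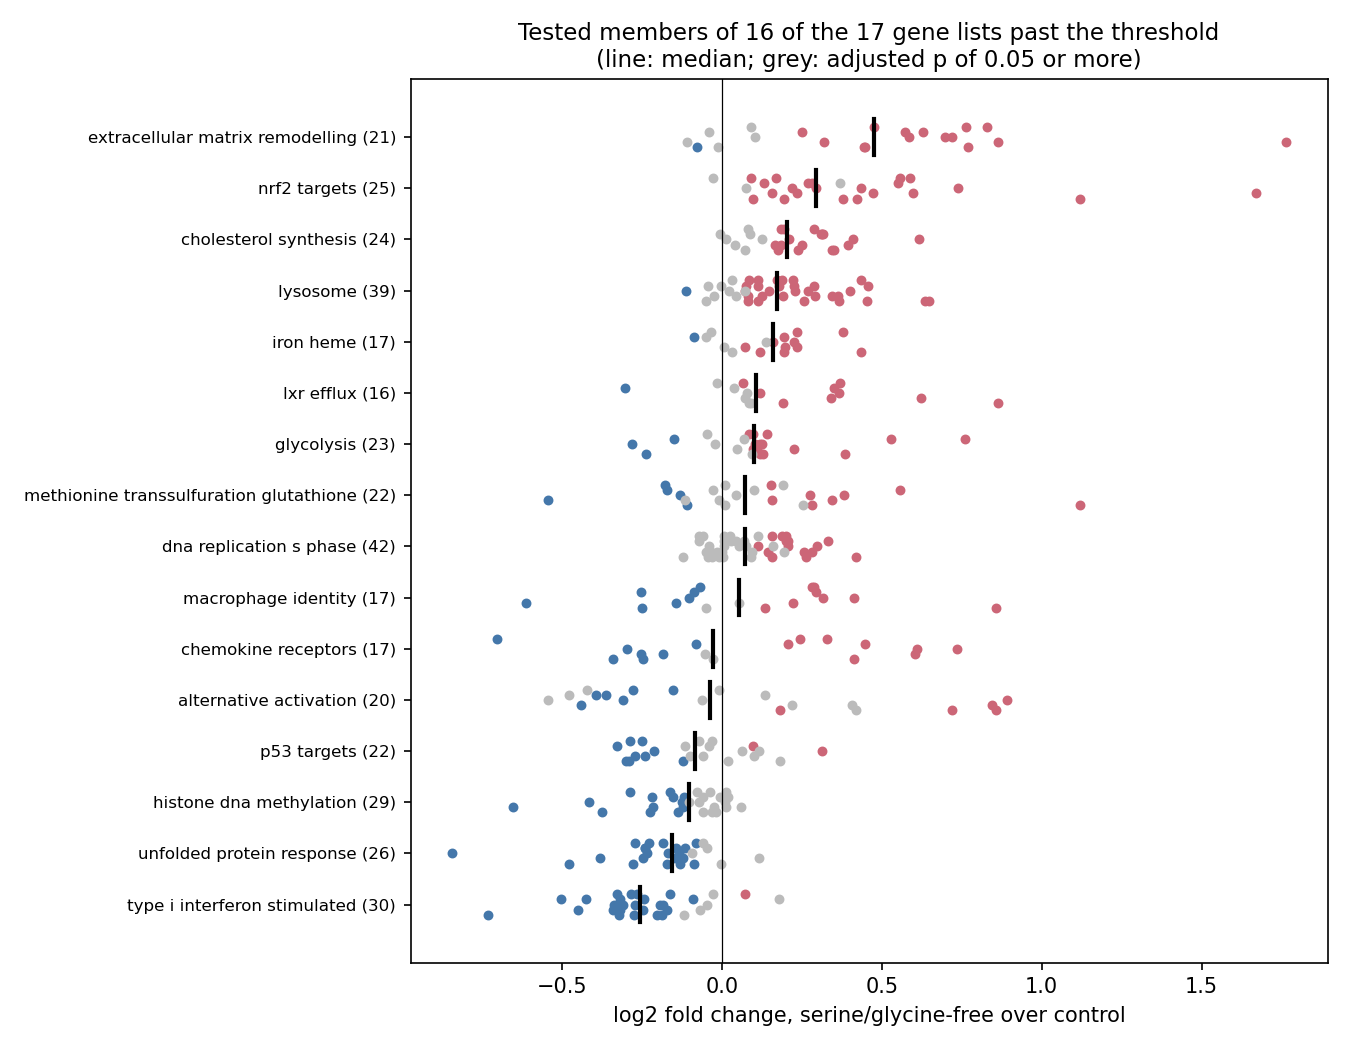
Log2 fold changes (horizontal axis) of the tested members of 16 of the 17 gene lists that passed camera at the preset correlation; each point is a gene, red where it rose, blue where it fell and grey where it did not pass, the line marks the median and the number in brackets counts tested members. Medians ran from -0.26 for type I interferon-stimulated genes to 0.48 for matrix remodelling genes.

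Type I interferon-stimulated genes fell: of 30, 1 rose, 24 fell and 5 did not pass (1 and 26 adjusted over the list alone, camera adjusted p = 6.0e-18). The nucleic acid sensor Zbp1 fell from 75.6 to 45.6 CPM (-0.73), Ddx58 by a log2 change of -0.34 and Ifit3 of -0.34. Of 26 unfolded protein response genes, 0 rose, 21 fell and 5 did not pass (1 and 22 adjusted over the list alone, camera adjusted p = 6.5e-10), with Pdia4 at -0.48 and the chaperone Hspa5 at -0.23. Of 22 p53 targets, 2 rose, 9 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.219 with an estimated correlation). Ccng1 (-0.30) and Cdkn1a (-0.27) fell and Plk2 rose (0.31). Of 29 histone and DNA methylation genes, 0 rose, 14 fell and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00074; adjusted p = 0.287 with an estimated correlation), including the demethylation enzymes Tet3 (-0.37), Tet2 (-0.41) and Kdm6b (-0.65). With each library's trend with gene length removed, that list's adjusted p was 0.0603. Of 30 ribosome biogenesis and mTORC1 genes, 1 rose, 9 fell and 20 did not pass, the same adjusted over the list alone (camera adjusted p = 0.10), with Npm1 (-0.17), Ncl (-0.16) and Nolc1 (-0.20) lower.

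Of 23 glycolysis genes, 15 rose, 3 fell and 5 did not pass (16 and 3 adjusted over the list alone, camera adjusted p = 0.0492; adjusted p = 0.341 with an estimated correlation and 0.110 with the length trend removed). The 3 members with the smallest p were Pfkfb3 (-0.24), Slc16a1 (-0.28) and Hk3 (0.22), and the list's call was lost when any of 6 of the 8 libraries was left out, with adjusted p up to 0.0709 (without serine/glycine-free replicate 4). Of 24 citric acid cycle genes, 3 rose, 3 fell and 18 did not pass, the same adjusted over the list alone (camera adjusted p = 0.539), with Idh1 (0.37) and Acod1 (0.30), the itaconate enzyme, higher and Ogdh lower (-0.11). Of 52 nuclear genes of oxidative phosphorylation, 13 rose, 2 fell and 37 did not pass, the same adjusted over the list alone (camera adjusted p = 0.112), with Uqcrb at 0.18, Atp5h at 0.13 and Ndufs8 at -0.19. With the length trend removed, 1 rose and 12 fell, the list's median went from 0.066 to -0.028 (adjusted p = 0.429), and Uqcrb (0.054, adjusted p = 0.260) and Atp5h (0.020, adjusted p = 0.671) did not pass. The list passed without serine/glycine-free replicate 2 (adjusted p = 0.0140) and without control replicate 1 (adjusted p = 0.0456). Of 22 hypoxia genes, 10 rose, 4 fell and 8 did not pass (12 and 5 adjusted over the list alone, camera adjusted p = 0.615): Ndrg1 fell from 2703 to 1602 CPM (-0.75), and Vegfa (0.62) and Egln3 (0.90) rose. Of 15 purine synthesis genes, 3 rose, 5 fell and 7 did not pass (3 and 6 adjusted over the list alone, camera adjusted p = 0.952, test direction up, median -0.055), with Adssl1 at 0.48, Aprt at 0.22 and Pfas at -0.20. Of 17 pyrimidine synthesis genes, 3 rose, 1 fell and 13 did not pass, the same adjusted over the list alone (camera adjusted p = 0.688), with Ctps2 at 0.25, Tyms at 0.28 and Dck at -0.16. Of 42 DNA replication genes, 15 rose, 0 fell and 27 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 0.0252; adjusted p = 0.219 with an estimated correlation and 0.0501 with the length trend removed), including Cdt1 (0.42), Pcna (0.26) and Mcm6 (0.21). Of 44 mitosis genes, 12 rose, 2 fell and 30 did not pass, the same adjusted over the list alone (camera adjusted p = 0.183), with Ccnb2 (0.33) and Nusap1 (0.34) higher and Kif11 lower (-0.30).

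The tested lists of markers of other cell types did not pass camera. Of 9 monocyte-like genes, 2 rose, 5 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.630). S100a4 rose (0.34), Spn fell (-0.21), and Plac8 went from 0.881 to 0.180 CPM. Plac8 had 63 reads in control and 13 in serine/glycine-free libraries, the latter close to what a count of 0 allows. Its log2 change lay between -2.89 and -1.83 without single libraries. Of 5 neutrophil genes, 2 rose, 1 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.539), with S100a8 at 0.755 and 1.87 CPM, Mmp8 at 4.03 and 6.01 CPM and Csf3r at 138 and 122 CPM in control and serine/glycine-free libraries. Of 6 dendritic cell genes, 1 rose, 3 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.112), with Tmem123 (-0.28), Fscn1 (-0.53) and Batf3 (-0.48) lower. Of 3 lymphoid genes, 0 rose, 1 (Cd79b, -0.41) fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.304). Of 7 osteoclast genes, 2 rose, 3 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.650, median -0.093, mean 0.084), with Atp6v0d2 higher (0.63) and Nfatc1 (-0.30) and Acp5 (-0.093) lower. The mast cell and basophil list had 1 tested gene, Hdc (0.99, rising from 0.713 to 1.43 CPM), the erythroid and megakaryocyte list 2 and the fibroblast list 2, none of these 4 past the threshold, and the nuclear RNA list 1, Snhg11 (0.031, adjusted p = 0.871).

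Short genes were higher and long genes lower without serine and glycine. Across 9772 genes of at least 5 CPM with a known length, log2 change and effective length had a rank correlation of -0.301, where genes are not independent replicates. In the eighth of genes with the shortest lengths the median log2 change was 0.076, and in the eighth with the longest -0.076. More genes were detected with at least 1 count without serine and glycine (14790 to 14819 per library) than in controls (14481 to 14562), and the 10 most abundant genes took 9.24% to 9.87% against 8.27% to 8.52% of counts.

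**Figure D3:**
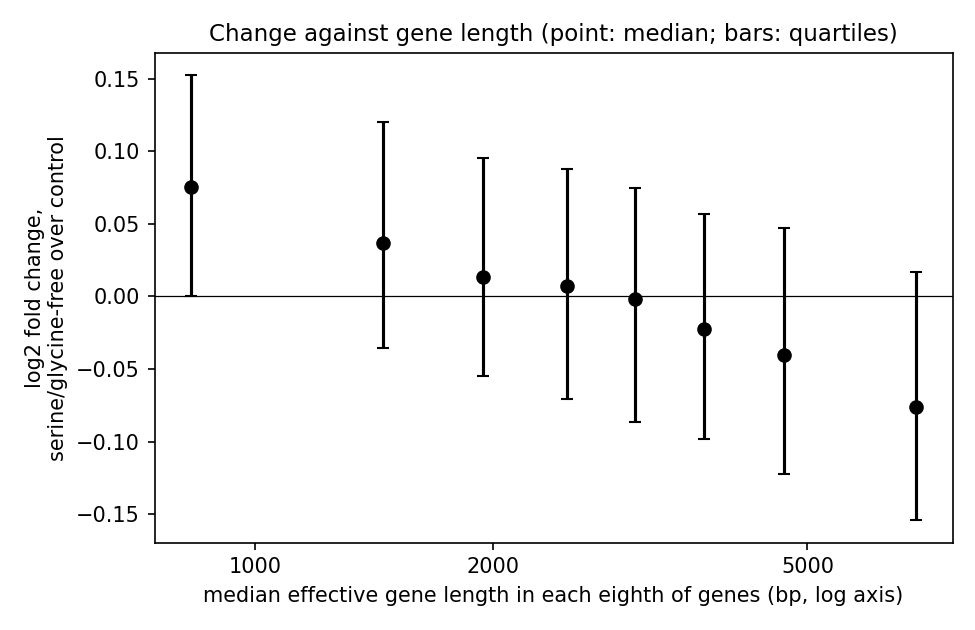
Median log2 fold change (vertical axis, points; bars give the quartiles) of 9772 genes split into eighths by effective length (horizontal log axis, in bp). The median falls from 0.076 in the shortest eighth to -0.076 in the longest.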

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

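Among the genes named in the text, totals and detected genes, 282 group values were examined for a library far from the other 3 of its group, by Dixon's ratio of the gap over the group's range, and 16 met this, where chance at about 1 in 20 gives 14.1. No biological explanation was tested for them. In serine/glycine-free libraries, the library apart was the lowest for Psat1 (77.4 CPM, replicate 3), Nfkbiz (518 CPM, replicate 4) and Dck (74.5 CPM, replicate 4). It was the highest for Tmeff1 (8.74 CPM, replicate 3), Slc16a1 (76.4 CPM, replicate 1), Ctsd (11279 CPM, replicate 4) and Acp5 (169 CPM, replicate 4). In control libraries, it was the lowest for Arl4c (31.5 CPM) in replicate 1, for Npc2 (513 CPM) and Sptssa (68.6 CPM) in replicate 3, and for Acod1 (207 CPM), Nfatc1 (87.0 CPM) and Acp5 (170 CPM) in replicate 4. It was the highest for Pik3cd (223 CPM, replicate 2), Kif11 (36.0 CPM, replicate 4) and Vegfa (16.1 CPM, replicate 2).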

How the results depend on the processing

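Removal of the length and expression trends was chosen after seeing the data. The 3882 changed genes (1855 higher, 2027 lower) stayed within 1.5 times under every alternative but a log2 change of at least 1, which left 81 (65 higher, 16 lower) by its construction. Leaving out each library gave 3384 to 3760 genes (1589 to 1794 higher, 1790 to 1966 lower) and 15 to 17 lists (10 to 12 higher, 5 to 5 lower). DESeq2 called 2966, sharing 2930 with edgeR, limma-voom 3813 and no filter 3901. With the length trend removed 3938 genes passed (1598 higher, 2340 lower), 3316 of them shared calls, and with the expression trend removed 3708. With the replicate number as a block, 3655 genes and 16 lists passed. Deviations of same-numbered libraries from their group means correlated at -0.154, 0.041, -0.048 and -0.227. No pairing by number was thus detected, and the labels do not say whether there was any. The 17 lists (12 higher, 5 lower) became 9 (6 higher, 3 lower) with an estimated correlation and 33 (21 higher, 12 lower) with fry, which tests each list against no change and not against other genes. Of 43 lists, 13 kept direction and call under all 17 alternatives, and 26 did when fry and the estimated correlation are set aside. Of 144 named genes, 136 kept both under all 17 alternatives. The 8 genes that did not include Tnf, whose adjusted p was 0.083 with library size only, 0.0774 with the block and 0.398 with the expression trend removed, where Acp5 (0.107) and Fasn (0.126) also lost their call. Ifi30 lost its call without a filter (0.0549), with DESeq2 (0.133) and with limma-voom (0.0609). With the length trend removed, Phgdh passed (log2 change -0.098), and Uqcrb, Atp5h, Fasn and Ifi30 did not. The lists that lost their call there were histone and DNA methylation, glycolysis (adjusted p = 0.110), macrophage identity (0.0875), methionine and glutathione (0.0516) and DNA replication (0.0501). Glycolysis also lost its call with RLE size factors (0.0519), at a mean of at least 5 CPM (0.0568) and with the block (0.0590). Lists gained a call too: amino acid transporters with the length (0.0120) or expression trend removed (0.0378), complement with the length trend removed (0.0199) or no filter (0.0349), and mTORC1 with no filter (0.0204). With the length trend removed and an estimated correlation together, amino acid transporters (0.145) and complement (0.119) did not pass. Autophagy passed with library size only (0.0451), no filter (0.0349) and the expression trend removed (0.0193), and oxidative phosphorylation with the last (0.0317). No result past its threshold turned direction. Among those not past it, Psph went to -0.0019 without a filter, -0.048 with the length trend and -0.033 with the expression trend removed, and lay between -0.039 (without control replicate 3, where it also turned) and 0.031 without single libraries. Direction also turned, with these adjusted p, for tRNA synthetases (0.971) and purine synthesis (0.920) without a filter. The IGF axis turned without a filter (0.825), with the length (0.587) and expression trend removed (0.775) and without serine/glycine-free replicate 3 or 4 or control replicate 3 (0.867 to 0.975 over all 8 libraries left out). The p38 list turned at a mean of at least 5 CPM (0.884) and with the length (0.973) and expression trend removed (0.946), as did monocyte-like genes at 5 CPM (0.750). With the length trend removed the citric acid cycle (0.973), oxidative phosphorylation (0.429) and purine (0.871) lists turned, the last also without serine/glycine-free replicate 1 or 4 or control replicate 3 (0.882 to 0.995 over all 8). The cause was not tested. Low genes were recovered less often in the simulation: of 1.2-fold changes, 4 of 27 (14.8%) were recovered below the median level of 543 reads and 37 of 39 (94.9%) above. With only 200 changed genes the adjustment was stricter there, so these shares do not give the recovery in the data.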

Other observations

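The gene lists below and the tests of gene length, GC content, depth and receptor genes were chosen after the results were seen; the splits of the samples and the threshold for the list of other SMAD-responsive genes were set before their results. Both lists of this paragraph were drawn up from rises already seen, so they show a pattern and do not test it. Of 27 tested genes of lipid-associated macrophages and disease-associated microglia, 22 rose, 1 fell and 4 did not pass. The fixed lists hold 16 of the 27, among them Trem2, Gpnmb, Spp1 and Lgals3. Of the 11 others, 8 rose, 1 fell and 2 did not pass, with Fabp4 (0.98), Cd9 (0.99) and Fabp5 (0.62) higher. Of 18 glutathione transferases and related detoxification enzymes, 13 rose, 1 fell and 4 did not pass, and 2 of the 18, Gsta3 (1.67) and Gstm1 (0.74), are also in the NRF2 list. Akr1b8 (0.94) and Mgst1 (0.69) rose, while Gstp1 stood at 0.00016 with non-whole counts in 62.5% of libraries.

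The rise of Id1, Id3 and Tgfbi came with other genes that answer to SMAD proteins, the transcription factors of TGF-beta and BMP signalling. Of 10 such others whose values had been seen, 6 rose, 0 fell and 4 did not pass, so this list shows the pattern and does not test it. The rises included the feedback inhibitors Smad6 (2.90, SE 0.20) and Smad7 (1.11, SE 0.14) and Id2 (0.95). Smad6 and Smad7 were low, with a mean log2 CPM of 1.36 and 1.77, below the 5 CPM asked of the largest changes. The 3 genes kept at least 0.965 of their log2 change once the trend with gene length was removed. Over eighths of genes by length the median log2 change ran only from 0.076 to -0.076, so a large loss could not occur. The share kept is therefore no test, and shows only that the trend is too small to account for these rises. SMAD-driven transcription is a candidate explanation: in 14 tested SMAD-responsive genes whose values had not been displayed, although they were known to be absent from a listing of the largest changes, 6 rose, 1 fell and 7 did not pass, with a median of 0.15. The list's p by camera was 0.0424, under the threshold set beforehand. That p was 0.101 with an estimated correlation, so the evidence is weak, and the medium itself, through another path, stays open.

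The fall of histone and DNA methylation genes coincided with their length, a median of 6542 bp against 2656 bp over tested genes. GC content and log2 change had a rank correlation of -0.033 across genes, which argues against a steady rise or fall with GC content. A trend of another shape and the GC content of this list were not examined. Removing the length trend moved the list's median log2 change from -0.10 (quartiles -0.16 and -0.026) to -0.058 (quartiles -0.11 and 0.0060) and its adjusted p to 0.0603. The call ended with the median at 0.560 of its former size. Of the other 16 lists past the threshold, 12 kept their call. In 10 of them the median lay on the side of the call, and the median ratio of list medians after and before removal was 1.02 (0.834 to 1.38), which argues against length as the whole cause of those 10. In alternative activation and chemokine receptors it lay against the call, so their ratio decides nothing. The other 4 of the 16 lost their call, with a median ratio of 0.642. Medians moved from 0.053 to 0.031 for macrophage identity (quartiles -0.10 and 0.29 before, -0.16 and 0.29 after) and from 0.072 to 0.046 for DNA replication (-0.0061 and 0.19, then -0.032 and 0.14). For methionine and glutathione they moved from 0.073 to 0.047 (-0.088 and 0.27, then -0.12 and 0.23), and for glycolysis from 0.10 to 0.078 (0.058 and 0.13, then 0.044 and 0.098). The calls of these 4, with adjusted p of 0.0183 to 0.0492 before, ended with the smaller medians. Length slopes per library ran from -0.054 to 0.0017 without serine and glycine and from 0.0042 to 0.040 in controls, so for the histone list and these 4 a length effect and the medium cannot be told apart.

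More genes were detected without serine and glycine. With every library thinned to 17565269 reads the groups stayed apart by 222 genes (14771 to 14804 against 14479 to 14549), which argues against sequencing depth. Evenly spread background reads, as from genomic DNA, could raise all low genes alike: 123 odorant, vomeronasal, trace amine and taste receptor genes with a mean of at most 3 reads had a ratio of 1.14 (95% interval from 2000 resamples of genes 0.876 to 1.47), against 1.23 for 4662 other genes at that level. With 269 receptor reads in all, background and the medium cannot be told apart.

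Of the 35 splits of the 8 libraries into 4 and 4, the real one gave 3882 genes and the highest other 1. Splits that exchanged 1 library called 0 genes, because the real difference then widens the spread within groups. The gene count therefore shows only that the real split ranks first of 35, and does not exclude a chance division. For the lists, 1 of 35 splits gave as many as 17, but the highest other gave 16. The 16 splits that exchanged 1 library between the groups, and so keep much of the contrast, called 10 to 16 lists, and the 18 that mixed the groups evenly called 0 to 2. The number of lists at the preset correlation therefore separates the real split by a margin of a single list.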
